A study of Mus musculus with 48 samples.

How the data were processed

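Spleens of mice immunized with sheep red blood cells (SRBC), an antigen that drives germinal center (GC) reactions, were the source of all samples. Mice carrying a c-Rel transgene (called transgenic here) were compared with mice without it (controls), 8 mice per genotype. Both genotypes carried 1 further allele, which, like some genes of the lists, is not reported here. c-Rel is a subunit of the transcription factor NF-kB, encoded in the mouse by Rel. From each mouse 3 populations were collected after magnetic pre-separation and flow sorting: naive B cells (high IgD, low IgM), GC B cells (B220 positive, IgD negative, low CD38, high CD95, GL7 positive) and plasma cells (low B220, CD138 positive). Every library was made from 1000 sorted cells. The labels give the same animal number to the libraries of 1 mouse, so that mice 1 to 4 and 9 to 12 were controls and mice 5 to 8 and 13 to 16 were transgenic.

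Per the labels' protocols, libraries were prepared as bulk SCRB-seq, a method that counts unique molecular identifiers (UMIs) near the 3′ end of messenger RNA. The authors aligned the reads with STAR to GRCm38.p5, per the submitters' processing notes, and deposited 1 table of UMI counts per gene, which was used here without change. The STAR version, the annotation release and the way UMIs were collapsed are not given in the sources used here. Because 1 tag stands for 1 molecule and comes from the 3′ end, counts were not divided by gene length, and transcript forms that share a 3′ end could not be told apart. The table held 20007 genes in 48 libraries. Ensembl identifiers were given symbols and GRCm38 coordinates from GENCODE M21, which named 19701 of them; the 306 without a symbol held 0.424% of the UMIs. Ighd, Iglc1, Iglc3, Bcl2a1a and Bcl2a1d, members of the gene lists, were not analysed here.

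Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust dispersion, TMM scaling, filterByExpr, Benjamini-Hochberg threshold 0.05). Genotypes were compared within each population with 1 library per mouse. Populations were compared in control mice, and differences between genotype effects were tested as contrasts in a fit of all 48 libraries. Means are in CPM, UMI counts scaled to a common library total, with totals corrected by TMM for genes tested with edgeR and as counted elsewhere, ± SD over 8 mice unless SE is written. Log2 fold changes come from the edgeR fit with its own small prior count, while a prior count of 2 was used for log2 CPM values. Where all libraries of a group held no UMI, a floor of 3 UMIs over that group was used. The groups, tests, gene lists and alternatives were set before the data were examined, except those named as chosen later.

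The 19 gene lists were NF-kB subunits and inhibitors, NF-kB target genes in B cells, the GC B cell program, GC light zone, GC dark zone, the plasma cell program, the unfolded protein response and secretion, the mature naive B cell program, MHC class II presentation, cell cycle, Myc targets and ribosome biogenesis, glycolysis, oxidative phosphorylation, the interferon response, apoptosis regulators, trafficking receptors, age-associated B cell genes, immunoglobulin constant genes, and stress and early response genes. Another 7 lists held markers of T cells, NK cells, monocytes with macrophages and neutrophils, dendritic cells, erythroid cells and platelets, and Y-linked genes. Lists with at least 3 tested members were compared with all other genes by limma 3.58.1 camera with a fixed correlation of 0.01 between genes, and again with a correlation estimated from the data; p values were adjusted over the lists of a comparison. Member counts are given at the threshold over all genes and adjusted over the list alone. Named genes were Rel, up to 10 per direction with the largest fold change among genes that passed at a mean of at least 10 CPM (without immunoglobulin or T cell receptor segments and genes known only by number), and up to 4 passing members per list. For populations the rule took up to 4 members per list and direction and up to 5 further genes per direction, and for differences between effects up to 5 per direction.

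Heavy chain isotypes were measured as shares of the UMIs of Ighm, Ighg1, Ighg2b, Ighg2c, Ighg3, Igha and Ighe in each library, with the switched share being all but Ighm. They were compared by exact permutation of the genotype over all 12870 splits of the mice, two-sided, adjusted over 24 tests. Library totals, gene numbers, mitochondrial and immunoglobulin shares and marker sums, as log2(CPM + 1) with a pseudocount of 1, were compared in the same way over 33 tests. Genotype effects in different populations were related by their correlation across genes, set against 100 splits of the 16 mice into groups of 8, the real split among them and the others drawn at random; the same splits were used for the numbers of called genes. Genes of 1 table are not independent replicates, so no p value was taken from a correlation across genes.

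Whether animal numbers pair libraries was checked by correlating deviations from the group mean over 5147 genes. Medians for libraries of the same mouse ran from −0.0015 to 0.039, and between 1 and 5 of 8 mice in a group were closest to their own library in another population, so the counts alone carried little sign of the pairing. The pairing rests on the labels, and fits with a term for the mouse were run as an alternative. Xist and Y-linked genes gave each of the 16 mice 1 sex in all of its libraries. Between libraries of a group, counts differed by more than sampling: over the 28 pairs of each group the median chi-square per degree of freedom was 1.24 and 1.26 in naive B cells, 1.53 and 1.71 in GC B cells, and 6.95 and 6.31 in plasma cells of control and transgenic mice. The dispersion of edgeR takes up this excess.

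The edgeR steps were tested on simulated data with known changes, drawn from the means, dispersions and library sizes of the deposited counts. Genotypes, and in the population comparisons both populations, were given common means before a small part of the genes was changed. At 1.5-, 2- and 4-fold they found 66.1, 98.3 and 100% of changed genes in naive B cells (2020 genes), 74.2, 98.3 and 100% in GC B cells (6233 genes) and 42.4, 94.8 and 100% in plasma cells (4316 genes), where 5.13, 6.29 and 6.16% of the calls were false. The population comparisons found 44.4, 86.9 and 100% (GC against naive B cells, 4390 genes), 54.2, 94.3 and 100% (plasma cells against naive B cells, 3169 genes) and 55.4, 95.3 and 100% (plasma cells against GC B cells, 5444 genes). Differences between genotype effects were found less often, at 9.38, 41.8 and 76.6% (GC against naive B cells, 7598 genes), 10.9, 32.8 and 73.8% (plasma cells against naive B cells, 7599 genes) and 12.5, 44.8 and 90.8% (plasma cells against GC B cells, 7599 genes). In the same order 3.65, 5.04 and 6.55% of the calls were false for the populations, and 5.68, 8.33 and 4.90% for the differences. Real populations differed in most tested genes, so the population values do not show how scaling deals with such differences. For the differences each gene was simulated with 1 dispersion over all populations, so unequal spread was not tested.

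Alternatives were RLE scaling, no expression filter, a filter at a mean of 10 UMIs, DESeq2 1.42.0, limma-voom with quality weights, immunoglobulin genes removed, a term for mice 1 to 8 against 9 to 16, counts thinned to equal depth, 1 fit of all 48 libraries, a covariate for Y-linked expression, a term for the mouse, each library left out in turn, plasma cells without control mice 9 and 10 (whose plasma cell titles carry another suffix than those of the other mice), and fry for the lists. Leaving out libraries with less than the median depth divided by 3, or with under 100 heavy chain UMIs, removed none. Chosen after the results were seen were an exact permutation test of Rel in all populations, the difference of isotype shares between populations, fits of mice 1 to 8 and of mice 9 to 16 alone, marker sums without 1 gene, and the patterns weighed in the closing part. Sequence reads, autoantibodies, cell numbers and other tissues were not analysed here.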

Results

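Expression was measured in 48 libraries of sorted spleen cells from 16 SRBC-immunized mice, 8 carrying the c-Rel transgene and 8 controls. Each mouse gave 1 library of naive B cells, 1 of GC B cells and 1 of plasma cells. Libraries held between 97993 and 159857 UMIs in naive B cells, between 401207 and 695137 in GC B cells and between 481229 and 794273 in plasma cells. Fewer genes could be tested in naive B cells (2131, against 6393 and 4538). Immunoglobulin genes took 50.3 ± 2.06% of the UMIs of control plasma cells and 49.7 ± 1.73% of those of transgenic plasma cells (n = 8 mice each). Total UMIs of GC B cells were 453600 ± 60965 in controls and 560380 ± 75238 in transgenic mice (two-sided exact permutation p = 0.00839, adjusted p = 0.0554 over 33 library tests).

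Rel encodes c-Rel (ENSMUSG00000020275, chromosome 11, 23736847 to 23770970) and was higher in transgenic GC B cells. It stood there at 35.8 ± 9.26 CPM against 16.9 ± 6.37 CPM in controls (n = 8 mice each, 160 against 61 UMIs, two-sided exact permutation p = 7.77e-04, adjusted p = 0.00233 over 3 populations). In plasma cells, which carried little Rel, 18 UMIs were found in 7 of 8 transgenic libraries and 1 UMI in 1 of 8 control libraries. This gave 3.55 ± 2.73 against 0.260 ± 0.735 CPM (exact permutation p = 0.00264, adjusted p = 0.00396). Naive B cells held 34.6 ± 22.3 CPM in transgenic and 40.7 ± 21.8 CPM in control mice (34 and 35 UMIs, exact permutation p = 0.584). Mice 1 to 8 and mice 9 to 16 were also compared as blocks of 4 against 4. In GC B cells the difference was 22.7 and 15.1 CPM (exact permutation p = 0.0286, the smallest possible, and 0.0857). It was 3.42 and 3.16 CPM in plasma cells (exact permutation p = 0.143 and 0.0286) and 0.374 and −12.5 CPM in naive B cells (p = 0.943 and 0.629). These exact tests were added after the expression filter had removed Rel from the edgeR tests of naive B cells and plasma cells. The table has no entry for the transgene, and tags come from the 3′ end, so a transgene transcript with another 3′ end would not be counted as Rel.

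**Figure D1:**
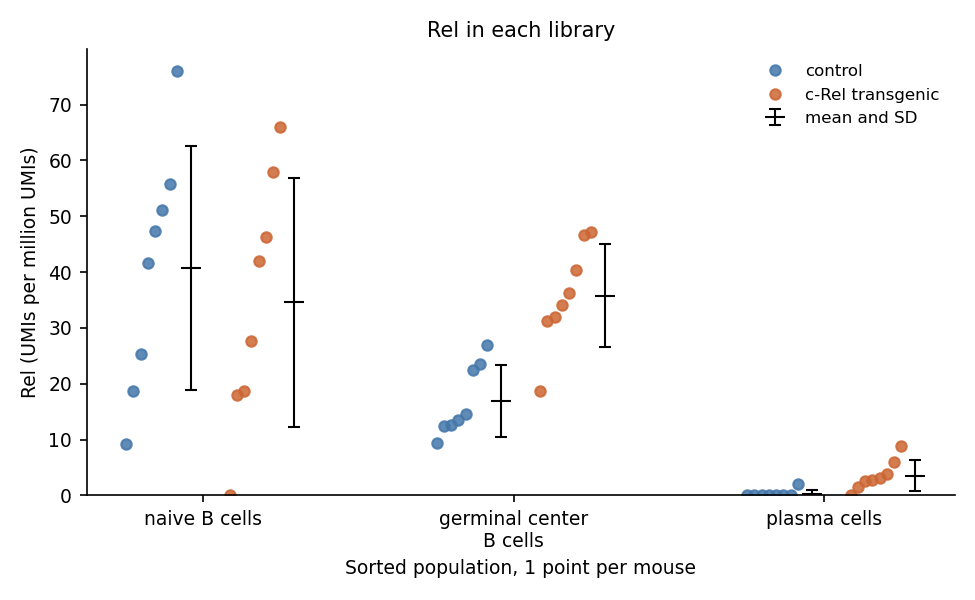
Rel in CPM (vertical axis) in naive B cells, GC B cells and plasma cells of control and transgenic mice. Each point is 1 library and the bars give the mean and SD of 8 mice, such as 16.9 ± 6.37 and 35.8 ± 9.26 CPM in control and transgenic GC B cells.

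In naive B cells the increases included Tgtp2 (ENSMUSG00000078921, chromosome 11, 49057194 to 49064206) and its near-identical neighbor Tgtp1, GTPases induced by interferon. Tgtp2 went from 116 ± 45.0 to 293 ± 101 CPM (log2 fold change 1.38, SE 0.20, adjusted p = 3.07e-07, n = 8 mice each) and Tgtp1 from 122 ± 59.5 to 277 ± 82.7 CPM (adjusted p = 1.33e-05). Serpina3g, an inhibitor of proteases inside lymphocytes, went from 116 ± 35.6 to 295 ± 104 CPM (log2 fold change 1.36, SE 0.20, adjusted p = 1.58e-07). How counts were shared between Tgtp1 and Tgtp2, and between Serpina3g and Serpina3f, is uncertain because their sequences are alike. H2-Q7 and H2-Q6, MHC class I genes that are also near copies, rose by log2 0.73 and 0.68 (adjusted p = 1.50e-09 and 7.78e-05). The transcription factor gene Irf1 (357 to 532 CPM, adjusted p = 0.00253) rose too. Smaller increases were found for Ly6a (log2 0.52), the MHC class I gene H2-T22 (0.47) and the immunoproteasome subunit Psmb9 (0.44, adjusted p = 0.0224, 0.0341 and 0.0150).

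Ier5, an early response gene, fell from 231 ± 77.5 to 123 ± 32.2 CPM (log2 fold change −0.91, SE 0.20, adjusted p = 0.00285), and Ezr, which links actin to the membrane, from 959 ± 116 to 717 ± 99.9 CPM (log2 fold change −0.43, SE 0.09, adjusted p = 0.00125). Arhgap9 (log2 −0.86), the actin-severing Gsn (−0.83) and Vpreb3 (−0.62) fell as well (adjusted p = 0.0150, 0.0150 and 0.0199). So did the cytokine gene Ltb (log2 −0.44), Emp3 (−0.46), Crip1 (−0.44) and Snn (−0.37, adjusted p = 0.0341, 0.0411, 0.0267 and 0.00839). Cd74, the invariant chain of MHC class II, fell by log2 0.15 (adjusted p = 0.0226).

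Of the 4 tested interferon genes 1 rose in naive B cells, and 2 rose adjusted over the list alone (camera adjusted p = 0.00198). With an estimated correlation the list had adjusted p = 0.0781. Of 17 unfolded protein response genes, which handle protein folding in the secretory pathway, none passed over all genes and 6 rose adjusted over the list alone. The list stood higher (camera adjusted p = 1.07e-05, and adjusted p = 0.112 with an estimated correlation), with Hspa5 at log2 0.25 and Dnajc3 at 0.66 (adjusted p = 0.164 and 0.0809). In the plasma cell program none of 9 passed and 4 rose adjusted over the list alone (camera adjusted p = 0.00360, and adjusted p = 0.220 with an estimated correlation). Jchain, which joins IgM and IgA multimers, had a log2 fold change of 1.06 (adjusted p = 0.394). Immunoglobulin constant genes gave none of 8, and Iglc2 adjusted over the list alone (camera adjusted p = 5.15e-05, and adjusted p = 0.274 with an estimated correlation). Immunoglobulin genes took 2.03 and 2.84% of the UMIs of control and transgenic naive B cells (exact permutation p = 0.0848). RNA of plasma cells, a candidate source of switched transcripts in these libraries, was not told apart from a change within naive B cells for these 3 lists. In MHC class II presentation Cd74 was the 1 gene of 11 to pass, by either adjustment. The median of that list was 0.0011 and its test pointed down (camera adjusted p = 0.663). None of 8 NF-kB subunits and inhibitors passed by either adjustment (camera adjusted p = 0.663).

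In all, edgeR called 24 genes in naive B cells, 13 higher and 11 lower in transgenic mice, 3 of them by more than 2-fold. Within the blocks of mice 1 to 8 and of mice 9 to 16 alone, 11 and 2 genes passed, and 13 and 15 passed without transgenic mouse 6 or 15. With all 48 libraries in 1 fit edgeR called 0 genes (592 at an unadjusted p under 0.05, with 7744 genes tested), so the 20 named genes lost the call there. DESeq2 on naive B cells called 13 (11 higher and 2 lower) and thinned counts gave 11 (9 higher and 2 lower), so most decreases were not called there. The loss of 1 library ended the call for 12 of the 20 named genes. Among them Emp3 lost it in 11 of 16 such fits, Ltb in 10, H2-T22 and Cd74 in 9, Ly6a and Crip1 in 8, Vpreb3 in 7, Psmb9 in 4, Arhgap9 and Gsn in 2 and Snn in 1.

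In GC B cells the largest increase was in Fscn1 (ENSMUSG00000029581, chromosome 5, 142960343 to 142973185), which encodes the actin-bundling protein fascin. It went from 41.2 ± 12.4 to 156 ± 38.5 CPM (log2 fold change 1.93, SE 0.16, adjusted p = 1.12e-10, n = 8 mice each). Rel was among the 10 largest, at log2 1.08 (SE 0.22, adjusted p = 0.00105 by edgeR). The interferon-induced genes Tgtp1 (35.4 ± 24.9 to 122 ± 51.3 CPM, adjusted p = 0.0117) and Ifi47 (52.5 ± 21.0 to 128 ± 36.4 CPM, adjusted p = 0.00197) rose, as did Tgtp2 (log2 1.72, adjusted p = 0.0198). Igtp and Bst2, also induced by interferon, rose by log2 1.09 and 1.09 (adjusted p = 2.49e-04 and 9.00e-04). The others were Shisa8 (log2 1.28), the lipase gene Mgll (1.20) and Pdk1, a kinase that holds back pyruvate oxidation (1.03, adjusted p = 3.55e-04, 2.53e-05 and 0.00464).

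Among the decreases in GC B cells, Cd2 (chromosome 3, 101275899 to 101287939), an adhesion receptor of lymphocytes, fell from 82.0 ± 11.9 to 34.4 ± 9.49 CPM (log2 fold change −1.29, SE 0.16, adjusted p = 7.01e-08). The embryonic globin gene Hbb-bh1 fell by log2 1.80 (adjusted p = 3.82e-04, 113 against 39 UMIs). Cd72, an inhibitory coreceptor of the B cell receptor, and Bank1, an adaptor of the same pathway, had log2 fold changes of −1.09 and −0.97 (adjusted p = 3.55e-04 and 0.00208). The transcriptional regulators Foxp1 (173 to 84.9 CPM) and Lmo2 (47.6 to 23.7 CPM) fell with adjusted p = 0.0276 and 0.00230. Ier5 (log2 −1.16), Nxpe2 (−1.26), Cyp4f18 (−1.24) and Pacsin1 (−0.99) were the other decreases among the 10 largest (adjusted p = 0.00302, 0.00119, 0.0330 and 5.28e-04).

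Glycolysis genes rose in transgenic GC B cells, 6 of 9 over all genes and 8 of 9 adjusted over the list alone. The camera test gave adjusted p = 2.48e-12, and adjusted p = 0.0259 with an estimated correlation. Aldoa (chromosome 7, 126795234 to 126800751) went from 1285 ± 93.3 to 1896 ± 257 CPM (log2 fold change 0.56, SE 0.06, adjusted p = 9.70e-08) and Tpi1 from 427 ± 42.4 to 669.6 ± 119 CPM (adjusted p = 1.19e-05). Ldha, which makes lactate, went from 757 to 1073 CPM (adjusted p = 0.00220). Eno1, Pkm and Pfkp were the other members that rose (log2 0.47, 0.31 and 0.31, adjusted p = 0.00116, 0.00370 and 0.0346).

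Of the Myc targets and ribosome biogenesis genes 10 of 21 rose in GC B cells, and 16 adjusted over the list alone (camera adjusted p = 1.73e-12). The list did not pass with an estimated correlation (adjusted p = 0.0728). Myc itself (chromosome 15, 61985391 to 61990374) went from 75.6 ± 22.0 to 133 ± 32.1 CPM (log2 fold change 0.81, SE 0.16, adjusted p = 0.00144). The nucleolar genes Nop58 and Nolc1 rose by log2 0.48 and 0.60 and the repair gene Apex1 by 0.48 (adjusted p = 1.54e-04, 3.37e-04 and 0.00123). Cell cycle genes stood higher as a list (camera adjusted p = 0.0498, and adjusted p = 0.532 with an estimated correlation). Of its 29 genes 2 rose by either adjustment, the replication clamp Pcna (log2 0.24, adjusted p = 0.00132) and Tyms, which makes thymidylate (log2 0.37, adjusted p = 0.0133).

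MHC class II genes fell in GC B cells, 8 of 11 over all genes and 9 adjusted over the list alone (camera adjusted p = 2.36e-10, and adjusted p = 0.0728 with an estimated correlation). Cd74 (chromosome 18, 60803848 to 60812652) went from 9375 ± 762 to 6812 ± 738 CPM (log2 fold change −0.46, SE 0.06, adjusted p = 8.79e-06). H2-Aa, H2-Eb1, H2-DMb2 and their transactivator Ciita had log2 fold changes of −0.29, −0.28, −0.28 and −0.46 (adjusted p = 3.27e-05, 3.55e-04, 0.00119 and 0.00720).

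In the GC B cell program 4 of 17 genes fell. Bcl6, the repressor that directs the GC state, went from 194 ± 23.1 to 139.6 ± 20.1 CPM (log2 fold change −0.48, SE 0.10, adjusted p = 7.80e-04). Cd81 (log2 −0.40, adjusted p = 0.00409) and Neil1 (log2 −0.29, adjusted p = 0.0451) were also among them. Adjusted over the list alone 10 fell and 2 rose, Ung and Gcsam (camera adjusted p = 0.00117, and adjusted p = 0.0728 with an estimated correlation). The GC receptor S1pr2 had 628 and 623 CPM (log2 −0.01, adjusted p = 0.932). Of the mature naive B cell program 5 of 14 fell by either adjustment (camera adjusted p = 3.23e-05, and adjusted p = 0.384 with an estimated correlation). They were Foxp1, Cd79a (log2 −0.39), Cd22 (−0.56), Ms4a1 (−0.29) and Fcmr (−0.63, adjusted p = 0.00924, 0.0136, 0.0223 and 0.0361).

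Of 7 interferon genes in GC B cells 2 rose, Bst2 and Zbp1 (log2 0.71, adjusted p = 0.00514), and 3 adjusted over the list alone (camera adjusted p = 0.0295, and adjusted p = 0.384 with an estimated correlation). Summed dendritic cell markers, which include Bst2, went from 6.15 to 6.71 log2(CPM + 1) (exact permutation p = 0.00311, adjusted p = 0.0256). Without Bst2 they were 5.70 and 6.02 (exact permutation p = 0.15). Summed T cell markers fell from 7.52 to 6.94 (exact permutation p = 3.11e-04, adjusted p = 0.00513). Most of them came from Lck, a kinase also transcribed in B cells (177 to 121 CPM, adjusted p = 2.51e-04 by edgeR), and without it the sum went from 3.83 to 3.09 (exact permutation p = 3.11e-04).

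Among NF-kB subunits and inhibitors in GC B cells Rel rose while the inhibitor Nfkbid (log2 −0.81, adjusted p = 0.00477) and Relb (log2 −0.46, adjusted p = 0.0212) fell. These were 3 of 11 genes by either adjustment (camera adjusted p = 0.581). Of 18 NF-kB target genes Icam1 rose by either adjustment (log2 0.28, adjusted p = 0.0391, camera adjusted p = 0.802). In the light zone list Myc and Icam1 rose, 2 of 11 by either adjustment (camera adjusted p = 0.279). In the dark zone list 2 of 13 fell, among them Foxo1 (log2 −0.45, adjusted p = 0.00261), with 1 up and 3 down adjusted over the list alone (camera adjusted p = 0.277).

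In the other lists for GC B cells few genes passed. Immunoglobulin constant genes stood higher, with none of 9 passing over all genes and Ighg1 adjusted over the list alone (camera adjusted p = 0.0498, and adjusted p = 0.532 with an estimated correlation). The proapoptotic Bcl2l11 rose (log2 0.69, adjusted p = 0.00824) and the survival gene Mcl1 fell (log2 −0.28, adjusted p = 0.0399), 2 of 10 apoptosis regulators by either adjustment (camera adjusted p = 0.840). In oxidative phosphorylation Atp5b rose (log2 0.20, adjusted p = 0.0128), 1 of 22 by either adjustment (camera adjusted p = 0.546). The trafficking receptor S1pr4 fell (log2 −0.63, adjusted p = 0.0399), 1 of 5, and 2 adjusted over the list alone (camera adjusted p = 0.0984). The chaperone Hsph1 rose (log2 0.64, adjusted p = 0.00633), 1 of 5 stress and early response genes by either adjustment (camera adjusted p = 0.793). The median of that list was −0.05 and its test pointed up. None of 15 plasma cell program genes, 20 unfolded protein response genes and 2 age-associated genes passed (camera adjusted p = 0.349 and 0.279 for the first 2 lists).

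In all, edgeR called 491 of 6393 genes in GC B cells, 229 higher and 262 lower, 18 of them by more than 2-fold. Within the blocks of mice 1 to 8 and of mice 9 to 16 alone 55 and 198 were called, and 747 without transgenic mouse 8. With 1 library left out, S1pr4 lost the call in 12 of 16 fits, Cyp4f18 in 11, Neil1 in 10 and Mcl1 in 9. Foxp1 and Icam1 lost it in 8, Ms4a1 in 5 and Relb in 3. Of the 51 named genes 6 lost the call with all 48 libraries in 1 fit and 4 without an expression filter. DESeq2 and the covariate for Y-linked expression ended it for 3 each, and thinned counts for 3 of 48 tested.

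**Figure D2:**
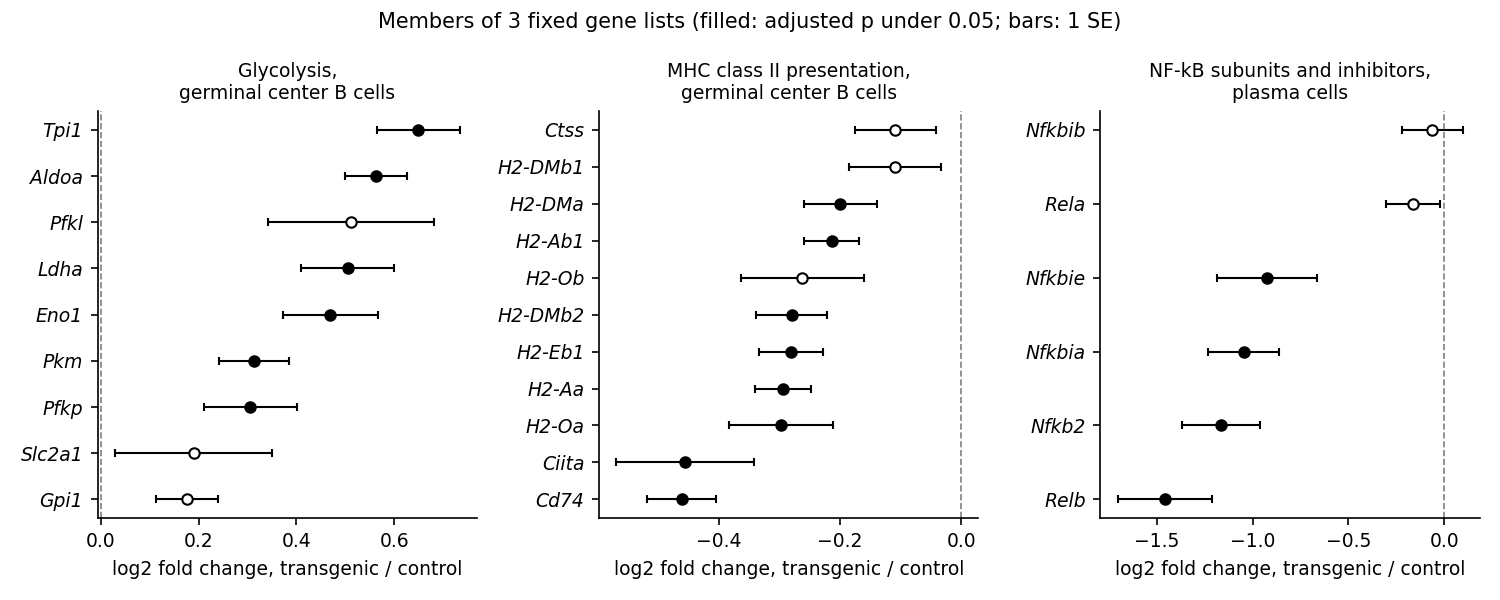
Log2 fold change between transgenic and control mice (horizontal axis) of members of 3 fixed lists, glycolysis and MHC class II presentation in GC B cells and NF-kB subunits and inhibitors in plasma cells. Points are estimates with 1 SE over 8 mice per genotype, filled where adjusted p was under 0.05, such as Aldoa at 0.56, Cd74 at −0.46 and Relb at −1.46.

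In plasma cells the largest decrease was in Wnt10a (ENSMUSG00000026167, chromosome 1, 74791516 to 74804179), a secreted Wnt ligand. It went from 43.9 ± 16.9 to 9.38 ± 3.06 CPM (log2 fold change −2.24, SE 0.24, adjusted p = 2.03e-09, n = 8 mice each). Serpina3g, higher in transgenic naive B cells, fell in plasma cells from 87.3 ± 35.2 to 22.3 ± 7.43 CPM (adjusted p = 2.27e-04), and its near copy Serpina3f fell too (log2 −1.51, adjusted p = 0.0341). Prg2, a granule protein gene also transcribed in plasma cells, went from 515 to 170.5 CPM (adjusted p = 4.70e-05). The folate hydrolase Ggh (log2 −1.89) and Apoe (−1.61) fell as well (adjusted p = 6.26e-09 and 0.0123). The transcriptional inhibitor Id2 and the IgM receptor Fcmr had log2 fold changes of −1.50 and −1.48 (adjusted p = 6.62e-06 and 3.71e-08).

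Among the increases in plasma cells were Tmem63b, an ion channel gene (39.9 ± 31.3 to 139 ± 57.4 CPM, log2 fold change 1.82, SE 0.42, adjusted p = 0.0163), and the cell cycle factor E2f2 (30.8 ± 7.54 to 64.8 ± 12.7 CPM, log2 fold change 1.08, SE 0.16, adjusted p = 3.89e-06). The interferon-induced genes Igtp, Tgtp1 and Tgtp2 rose by log2 1.04, 1.47 and 1.41 (adjusted p = 2.02e-04, 0.00219 and 0.00245). Pik3r5 (log2 1.21), Scimp (1.11) and the proliferation marker Mki67 (1.09) rose too (adjusted p = 6.05e-06, 0.0146 and 0.00243). The chemokine receptor Cxcr3 (log2 1.06, adjusted p = 0.0191) and the protease inhibitor Slpi (log2 1.47, adjusted p = 0.0442) completed the 10 largest.

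NF-kB subunits and inhibitors fell in transgenic plasma cells, 4 of 6 by either adjustment. The camera test gave adjusted p = 9.43e-07, and adjusted p = 0.0368 with an estimated correlation. Relb (chromosome 7, 19606217 to 19629438) and Nfkb2 encode subunits of the alternative pathway. Relb went from 45.9 ± 18.3 to 16.7 ± 6.25 CPM (log2 fold change −1.46, SE 0.25, adjusted p = 2.27e-04) and Nfkb2 from 55.8 to 25.0 CPM (adjusted p = 1.96e-04). The inhibitor gene Nfkbia (chromosome 12, 55489410 to 55492647) went from 539 ± 117 to 262 ± 75.7 CPM (log2 fold change −1.05, SE 0.18, adjusted p = 0.00274), and Nfkbie fell too (log2 −0.92, adjusted p = 0.0222). Of 10 NF-kB target genes Gadd45b rose (log2 0.50, adjusted p = 0.0484) and the cytokine subunit Ebi3 fell (log2 −0.85, adjusted p = 6.41e-04). Adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.149).

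In the mature naive B cell program 5 of 10 genes fell in plasma cells by either adjustment (camera adjusted p = 5.14e-05, and adjusted p = 0.0368 with an estimated correlation). Besides Fcmr they included Foxp1 (60.0 to 27.8 CPM), Cd79a (log2 −0.39) and Ms4a1 (−0.44, adjusted p = 1.26e-05, 0.00231 and 0.0492). Summed T cell markers fell beside these lists, from 7.66 to 7.17 log2(CPM + 1) (exact permutation p = 7.77e-04, adjusted p = 0.00855). Much of that sum came from Cd28 (78.8 and 91.8 CPM), which did not fall, and without it the sum went from 6.96 to 5.69 (exact permutation p = 1.55e-04). The T cell adaptor Lat was at log2 −1.41 (adjusted p = 3.89e-05) by edgeR, and without Lat alone the sum went from 7.46 to 7.07 (exact permutation p = 0.00357). Whether less T cell RNA adds to the decreases in plasma cells was not tested. Summed dendritic cell markers rose from 7.39 to 8.07 (exact permutation p = 3.11e-04, adjusted p = 0.00513). Without Bst2 they were 2.09 and 2.68 (exact permutation p = 0.145).

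Of the plasma cell program 6 of 22 genes fell and 1 rose, with 8 and 4 adjusted over the list alone (camera adjusted p = 0.0836). Jchain (chromosome 5, 88519809 to 88527891) fell from 59261 to 40051 CPM (log2 −0.57, adjusted p = 0.00486) and Ly6d by log2 1.19 (adjusted p = 0.00360). Sdc1, the CD138 antigen used for sorting, fell by log2 0.28 (adjusted p = 0.0123). The plasma cell regulators Prdm1 and Xbp1 had log2 fold changes of −0.13 and −0.18 (adjusted p = 0.679 and 0.117). In the unfolded protein response list Hspa5 (2338 to 2938 CPM) and the ubiquitin ligase Syvn1 (log2 0.26) rose, 2 of 24 (adjusted p = 0.00674 and 0.0232). Adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.00882, and adjusted p = 0.298 with an estimated correlation).

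Of 17 cell cycle genes in plasma cells 3 rose, E2f2, Mki67 and Ccne1 (log2 0.83, adjusted p = 0.00748), and 4 adjusted over the list alone. The list stood higher (camera adjusted p = 9.43e-07, and adjusted p = 0.191 with an estimated correlation). In MHC class II presentation Cd74 (3529.9 to 2315 CPM) and the protease Ctss (1124 to 540.1 CPM) fell, 2 of 9 (adjusted p = 8.16e-09 and 1.01e-05). Adjusted over the list alone 3 fell and 1 rose (camera adjusted p = 0.0229, and adjusted p = 0.216 with an estimated correlation). Of 6 interferon genes 2 rose, among them Bst2 (log2 0.60, adjusted p = 1.53e-04), with 3 up and 1 down adjusted over the list alone (camera adjusted p = 0.0800). Among 9 trafficking receptors Cxcr3 and the integrin Itga4 rose (log2 0.38, adjusted p = 0.0484 for Itga4) and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.202). Of 2 age-associated genes Cxcr3 rose and Fcer1g fell (log2 −1.19, adjusted p = 0.0469).

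Further lists in plasma cells moved by few genes. The GC coactivator Pou2af1 (log2 −0.35, adjusted p = 0.00117) and Cd81 (log2 −0.25, adjusted p = 0.0117) fell of 6 GC program genes, with 1 up and 2 down adjusted over the list alone. Median and mean of that list were 0.02 and 0.03, and its test pointed down (camera adjusted p = 0.676). Light zone genes stood lower with Nfkbia falling of 3, by either adjustment (camera adjusted p = 0.00488, and adjusted p = 0.145 with an estimated correlation). Of 4 dark zone genes Mki67 rose by either adjustment (camera adjusted p = 0.162). None of 13 Myc targets passed, while the list stood higher (camera adjusted p = 0.0233, and adjusted p = 0.160 with an estimated correlation). No gene passed over all genes in glycolysis (9), oxidative phosphorylation (21), apoptosis regulators (8) or stress and early response genes (6). Adjusted over the list alone 2 glycolysis genes rose and 1 apoptosis regulator fell (camera adjusted p = 0.161 and 0.735).

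In all, edgeR called 288 of 4538 genes in plasma cells, 105 higher and 183 lower, 55 of them by more than 2-fold. The blocks of mice 1 to 8 and of mice 9 to 16 alone gave 71 and 106, and 196 were called without the libraries of control mice 9 and 10, whose titles carry another suffix. Without these 2 libraries 12 of 45 named genes lost the call: Tmem63b, Slpi, Cxcr3, Serpina3f, Gadd45b, Cd81, Sdc1, Syvn1, Ccne1, Itga4, Fcer1g and Iglc2. With 1 library left out, Iglc2 lost it in 13 of 16 fits, Slpi and Gadd45b in 12, Fcer1g in 11, Serpina3f and Itga4 in 10, Nfkbie in 6 and Syvn1 in 2. Thinned counts ended it for Gadd45b, Itga4 and Iglc2.

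Plasma cells of transgenic mice carried a larger share of switched heavy chain transcripts. Ighm (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730), the IgM heavy chain, made up 42.3 ± 9.80% of heavy chain constant UMIs in controls and 14.1 ± 4.25% in transgenic mice (n = 8 mice each). The switched share thus went from 57.7% to 85.9%, by 28.2 points (two-sided exact permutation p = 1.55e-04, the smallest possible, adjusted p = 0.00186 over 24 tests). The ranges of the mice did not overlap, from 45.5 to 78.2% in controls and from 80.6 to 91.6% in transgenic mice. Ighg1 went from 5.49 ± 4.04% to 15.7 ± 5.62% and Ighg2c from 10.4% to 18.6% (exact permutation, adjusted p = 0.0112 and 0.0218). Without control mice 9 and 10 Ighg2c did not pass (adjusted p = 0.0541) and Ighg3 did (adjusted p = 0.0217). The shares of Ighg2b (13.5 and 20.9%, adjusted p = 0.0814), Ighg3 (5.49 and 2.31%, adjusted p = 0.0625), Igha (22.8 and 28.0%, adjusted p = 0.316) and Ighe (0.0278 and 0.289%, adjusted p = 0.0518) did not pass. Ighg2b and Ighg2c are close in sequence, so their separate shares are uncertain. Within the blocks of mice 1 to 8 and mice 9 to 16 the switched share differed by 25.0 and 31.4 points (exact permutation p = 0.0286 each, the smallest possible with 4 against 4). Measured against all genes, Ighm fell by log2 1.55, Iglc2 fell by log2 0.96 and Igkc fell by log2 0.34 in plasma cells (adjusted p = 6.59e-04, 0.0476 and 0.00702 by edgeR). These were 3 of 8 immunoglobulin constant genes, with 4 down and 2 up adjusted over the list alone (camera adjusted p = 0.369).

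GC B cells showed a smaller shift, from 60.6 ± 4.86% to 68.7 ± 4.53% switched, by 8.11 points (exact permutation p = 0.00342, adjusted p = 0.0137). Switched transcripts in GC B cell libraries stood at a median of 4205.5 CPM, 1.90% of the plasma cell level. RNA of plasma cells was not told apart from a change within GC B cells. Ighg1 was at 8.84% and 11.6% and Igha at 17.0% and 20.4% (adjusted p = 0.0112 and 0.0233). Within the blocks of mice 1 to 8 and mice 9 to 16 the switched share of GC B cells differed by 3.62 and 12.6 points (exact permutation p = 0.257 and 0.0286). In naive B cells, sorted for IgD, switched transcripts were 51.0 ± 8.85% and 60.3 ± 6.02% of 745 to 4583 heavy chain UMIs per library (exact permutation p = 0.0263, adjusted p = 0.0541). Their block values were 6.95 and 11.7 points (exact permutation p = 0.371 and 0.0571). The shift in plasma cells was larger than that in GC B cells by 20.1 points (exact permutation p = 7.77e-04, adjusted p = 0.00932 over 24 tests). It was larger than that in naive B cells by 18.8 points (adjusted p = 0.0336), and both tests were chosen after the shares were seen.

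**Figure D3:**
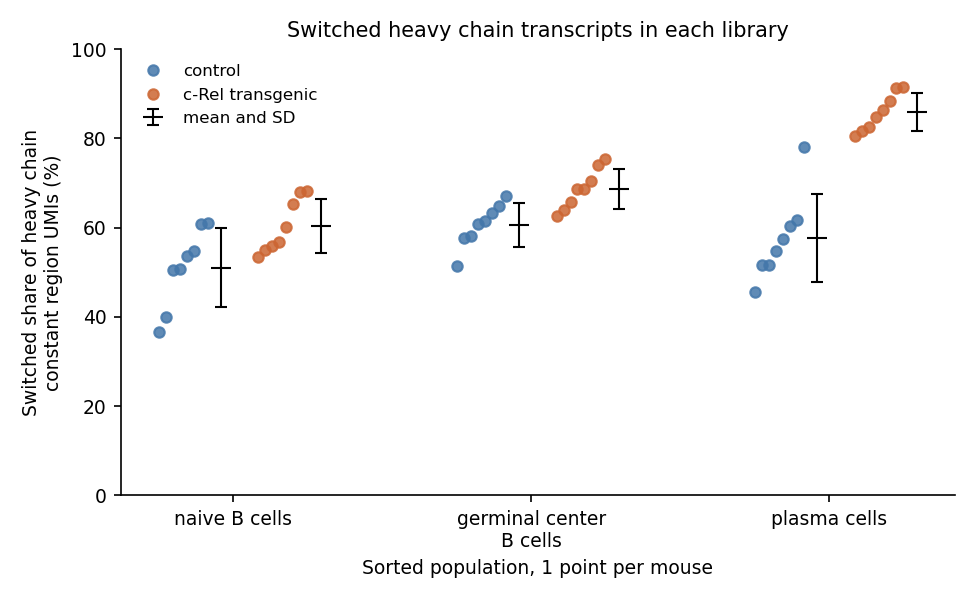
Switched share of heavy chain constant UMIs in percent (vertical axis) in naive B cells, GC B cells and plasma cells of control and transgenic mice. Each point is 1 library and the bars give the mean and SD of 8 mice, with means of 57.7 and 85.9% in control and transgenic plasma cells.

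Tgtp1 and Tgtp2 rose and Cd74 fell in all 3 populations. Across genes, which are not independent replicates, the genotype effects in GC B cells and plasma cells correlated at r = 0.232 (rho = 0.185, 4056 genes). Of the 100 splits of the mice, 2 gave an r as large, the real split among them. In both populations 15 genes were higher and 24 lower, where 3.59 and 6.09 would be found for independent lists of these sizes. That expectation does not allow for the mice that the populations have in common. Shared increases included Ifi47, Igtp and Bst2, and shared decreases Foxp1, Fcmr, Relb and the B lymphoid kinase Blk. Another 6 genes changed in opposite directions, Rpl8, Top1, Napsa, Btg2, Rgs14 and Pld4. Naive and GC B cells correlated at r = 0.320 (rho = 0.251, 2061 genes; 2 of 100 splits as large with the real one), with 4 genes higher and 4 lower in both (0.776 and 0.815 for independent lists). Naive B cells and plasma cells correlated at r = 0.103 (rho = 0.114, 1959 genes; 6 of 100 splits as large with the real one), with 3 genes higher and 2 lower in both (0.325 and 0.528 for independent lists). Serpina3g, Ly6a and B2m changed in opposite directions there.

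**Figure D4:**
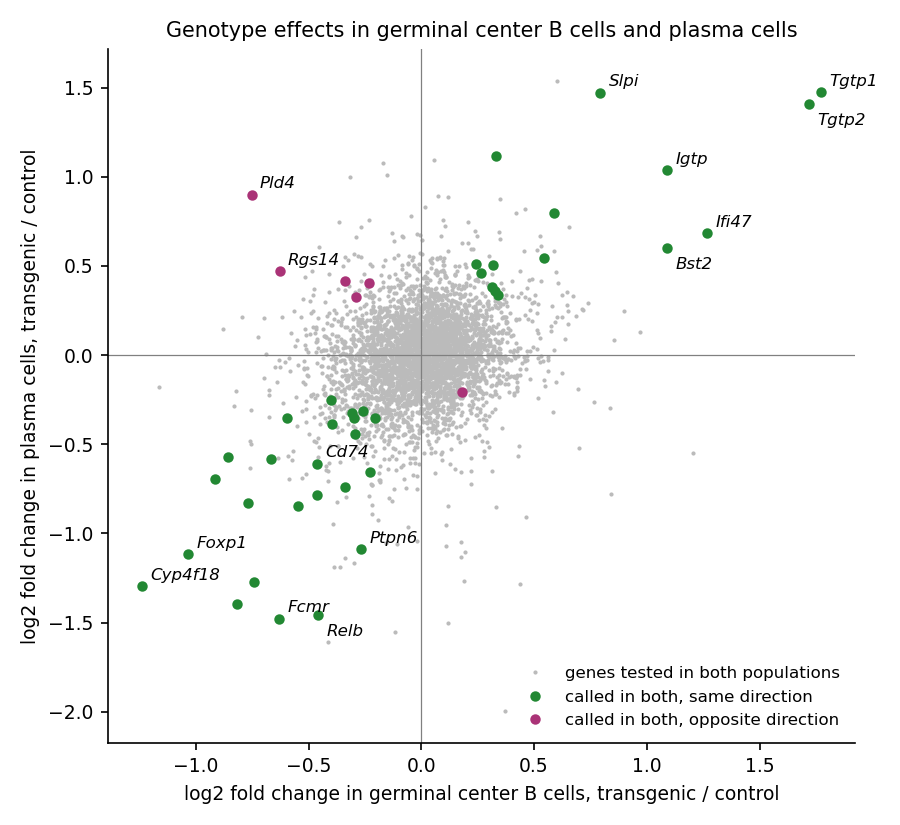
Log2 fold change between transgenic and control mice in GC B cells (horizontal axis) and plasma cells (vertical axis), 1 point per gene tested in both (4056 genes). Genes called in both are colored, 39 in the same direction in green and 6 in opposite directions in purple.

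Genotype effects were also compared between populations, in the fit of all 48 libraries. That fit gives each gene 1 dispersion over the 3 populations. Plasma cell libraries spread more than the others (median chi-square per degree of freedom 6.95 and 6.31 in control and transgenic mice). The p values and counts of these differences thus do not measure the spread of plasma cells alone. They may be too favorable where plasma cells are compared. Against naive B cells, the effect in GC B cells was more positive for Aldoa (log2 difference 0.61, adjusted p = 2.86e-04) and more negative for Fcrla (−0.63, adjusted p = 0.00166). Cd38, a surface enzyme low on GC B cells (−1.66, adjusted p = 0.00333), Cd72 (−1.34, adjusted p = 0.00333) and the actin-binding Cotl1 (−0.57, adjusted p = 0.00828) were more negative too. Phf10 also passed (adjusted p = 0.00686), with no UMI in the 8 control naive libraries and 16 UMIs in 7 transgenic ones. Against the floor of 3 UMIs Phf10 was 4.73-fold higher in transgenic naive B cells, without allowance for sampling of the 16 UMIs. For plasma cells against naive B cells the most negative by adjusted p were Ctss (−1.12, adjusted p = 3.52e-15), the phosphatase Ptpn6 (−1.15, adjusted p = 7.99e-12) and Ly6e (−0.73, adjusted p = 1.20e-08). Serpina3g (−3.37, adjusted p = 2.45e-06) and Ptprcap (−0.81, adjusted p = 3.23e-06) came next. The most positive were Fgd2 (1.18, adjusted p = 0.00158), Emp3 (0.71, adjusted p = 0.00369), Vpreb3 (0.99, adjusted p = 0.00671), Arid3a (1.46, adjusted p = 0.0151) and Ssb (1.68, adjusted p = 0.0164). For plasma cells against GC B cells E2f2 (1.24, adjusted p = 9.61e-07), the topoisomerase Top1 (0.63, adjusted p = 5.78e-05) and Pld4 (1.65, adjusted p = 1.02e-04) led upward. Mxd4 (0.90, adjusted p = 4.09e-04) and H2-Eb1 (0.47, adjusted p = 7.39e-04) followed. Downward they were Ctss (−0.96, adjusted p = 1.37e-11), Ly6e (−0.68, adjusted p = 1.76e-07), Aldoa (−0.66, adjusted p = 8.56e-07), Ptpn6 (−0.83, adjusted p = 9.79e-07) and Rapgef1 (−0.95, adjusted p = 1.42e-06).

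By list, the effect on glycolysis was more positive in GC B cells than in naive B cells, with Aldoa of 10 genes passing and 3 adjusted over the list alone (camera adjusted p = 8.12e-04, and adjusted p = 0.0458 with an estimated correlation). That on MHC class II presentation was more negative, with none of 11 passing and 8 adjusted over the list alone (camera adjusted p = 9.45e-08, and adjusted p = 0.0303 with an estimated correlation). NF-kB subunits and inhibitors were more negative in plasma cells than in GC B cells, 3 of 12 (camera adjusted p = 1.31e-04, and adjusted p = 0.00666 with an estimated correlation). Against naive B cells 3 were more negative and 1 more positive (camera adjusted p = 4.39e-04, and adjusted p = 0.0193 with an estimated correlation). Adjusted over the list alone these were 5 and 1 in either comparison. In all, edgeR called 10 genes for GC against naive B cells (1 more positive, 9 more negative), 90 for plasma cells against naive B cells (12 and 78) and 122 for plasma cells against GC B cells (41 and 81). With a term for the mouse as a block they were 12, 86 and 148, with DESeq2 30, 110 and 153, and with thinned counts 8, 36 and 16. Of the genes named above and tested with thinned counts, 2 of 5 (Fcrla and Cd38), 4 of 9 (Fgd2, Emp3, Vpreb3 and Arid3a) and 6 of 10 (E2f2, Pld4, H2-Eb1, Aldoa, Ptpn6 and Rapgef1) lost the call.

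In control mice GC B cells differed from naive B cells by markers of the GC state. The receptor S1pr2 (chromosome 9, 20962361 to 20976781), which holds cells in the follicle, went from 14.6 ± 13.1 to 639.6 ± 59.0 CPM (log2 fold change 5.38, SE 0.21, adjusted p = 3.31e-42, n = 8 mice). Fas rose by log2 3.93 (adjusted p = 2.15e-15), but it encodes CD95, for which GC B cells were sorted, so it is no independent marker. The chemokine receptor Ccr7 and the survival gene Bcl2 had log2 fold changes of −6.76 and −5.89 (adjusted p = 3.42e-39 and 6.21e-24). Gatm, E2f8, Arhgap8 and Sapcd2 had no UMI in control naive B cells and were at least 32.7, 22.0, 20.5 and 19.3-fold higher in GC B cells. Cnn3 (log2 −7.69) was also among the largest changes, with Rassf6, Plaur and S100a10, which had too few UMIs in the lower population for a fold to be given.

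By list, 16 of 17 GC program genes and all 28 tested cell cycle genes rose in GC B cells (Plk1 by log2 5.47, Mki67 by 4.63). So did 18 of 21 oxidative phosphorylation genes (Atp5a1 by log2 1.02) and 10 of 12 dark zone genes (1 fell). By contrast 18 of 20 naive program genes (1 rose), all 11 MHC class II genes (H2-Aa at log2 −1.50) and 12 of 13 trafficking receptors (1 rose) fell. NF-kB subunits and inhibitors fell in 8 of 9 cases (Nfkbia at log2 −1.26) and interferon genes in 6 of 7. All these counts were equal adjusted over the list alone. The camera test of each of these lists passed with an estimated correlation, except interferon (adjusted p = 0.200 with an estimated correlation). Between GC and naive B cells edgeR called 2667 of 4593 genes, 1334 higher and 1333 lower in GC B cells, and 2660 with the mouse as a block.

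Plasma cells of control mice differed from naive B cells by secretory genes. Xbp1, the transcription factor of the secretory response, rose from 243 ± 64.4 to 6813 ± 407 CPM (log2 fold change 4.81, SE 0.10, adjusted p = 2.93e-48, n = 8 mice). Jchain rose by log2 6.91, and the survival receptor gene Tnfrsf17 stood at 2.42 and 437 CPM (adjusted p = 1.02e-09 and 2.74e-13). Prg2 rose by log2 7.80, and Ly6c1 and Ly6c2, near copies of each other, by 7.39 and 6.91. Hhex (log2 −6.44) and Fcer2a (−6.23) fell, as did Zfp318 and Cnr2, which had too few UMIs in plasma cells for a fold to be given. The plasma cell program rose in 21 of 22 genes (Ly6d fell), the unfolded protein response in all 23 tested (Hspa5 by log2 3.08), immunoglobulin constant genes in all 8, and oxidative phosphorylation in 18 of 21. All 19 naive program genes (Ms4a1 at log2 −3.25), 10 of 11 MHC class II genes (Ctss rose, log2 0.80) and 10 of 12 trafficking receptors (1 rose) fell. These counts were equal adjusted over the list alone. Their camera tests passed with an estimated correlation, except oxidative phosphorylation (adjusted p = 0.257 with an estimated correlation). Between plasma cells and naive B cells edgeR called 2499 of 3647 genes (1244 higher, 1255 lower), 2505 with the mouse as a block and 1522 of 2101 tested without control mice 9 and 10.

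Against GC B cells, control plasma cells had more Sdc1 (3.33 to 741 CPM, log2 fold change 7.72, SE 0.15, adjusted p = 4.23e-49, n = 8 mice) and Ckap4 (log2 8.31, adjusted p = 5.15e-40). Sdc1 encodes CD138, for which plasma cells were sorted, so it is no independent marker. Control plasma cells had less Bcl6 (log2 −5.54, adjusted p = 4.97e-27) and the ETS factor Spib (log2 −5.57, adjusted p = 1.86e-45). Tmem176a (log2 8.11) was also among the largest changes, with H1fx, Ackr4 and Havcr1, which had too few UMIs in plasma cells for a fold to be given. All 22 plasma cell program genes, all 24 unfolded protein response genes and 5 of 8 interferon genes (Bst2 by log2 4.60) rose. Of the cell cycle list 28 of 29 fell (29 adjusted over the list alone). So did 14 of 17 GC program genes (2 rose), 12 of 13 dark zone genes and 9 of 11 MHC class II genes (1 rose), with equal counts adjusted over the list alone. Their camera tests passed with an estimated correlation. NF-kB subunits and inhibitors went both ways, Nfkbia at log2 2.09 and Nfkbid at −2.48, with 3 up and 4 down of 10 by either adjustment. The median of that list was 0.20 and its mean −0.04 (camera adjusted p = 0.940). Between plasma cells and GC B cells edgeR called 3937 of 5708 genes, 1961 higher and 1976 lower in plasma cells, and 3948 with the mouse as a block.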

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

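The splits of the samples were set before the data were examined, while the patterns weighed here, their tests and the differences of isotype shares between populations were chosen after the results were seen.

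In 1 of 100 splits, the real one, as many genes were called as in each real comparison. This is the smallest share that 100 splits can give, so for the genotype counts and their differences a chance division is unlikely but not excluded. For the populations the outcome was fixed in advance, because a split that mixes populations calls fewer genes, so nothing is concluded there. The genotype gave 24 genes in naive B cells (highest other split 2), 491 in GC B cells (43) and 288 in plasma cells (107), with the highest other values of GC B cells and plasma cells coming from a single split, which kept 1 of 8 transgenic mice in place and was thus close to the real one with the genotypes exchanged. The populations gave 2667 genes for GC against naive B cells (1439), 2499 for plasma cells against naive B cells (1775) and 3937 for plasma cells against GC B cells (2794), where the other splits with any calls had 14 of 16 libraries in their real place and those with 12 or fewer called 0 genes. Differences between genotype effects gave 10 genes for GC against naive B cells (2), 90 for plasma cells against naive B cells (22) and 122 for plasma cells against GC B cells (56).

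Genotype effects of single genes differed between populations by a test of the difference itself, in the fit with 1 dispersion per gene over the 3 populations. GC and naive B cells differed in Aldoa (0.61), Fcrla (−0.63), Cd38 (−1.66), Cd72 (−1.34), Phf10 (−5.69, which depends on the prior count since control naive B cells had no UMI) and Cotl1 (−0.57), as log2 differences. Plasma cells and naive B cells differed in Fgd2 (1.18), Emp3 (0.71), Vpreb3 (0.99), Arid3a (1.46), Ssb (1.68), Ctss (−1.12), Ptpn6 (−1.15), Ly6e (−0.73), Serpina3g (−3.37) and Ptprcap (−0.81). Plasma cells and GC B cells differed in E2f2 (1.24), Top1 (0.63), Pld4 (1.65), Mxd4 (0.90), H2-Eb1 (0.47), Ctss (−0.96), Ly6e (−0.68), Aldoa (−0.66), Ptpn6 (−0.83) and Rapgef1 (−0.95). With thinned counts the call was lost for Fcrla and Cd38 (2 of 5 tested), for Fgd2, Emp3, Vpreb3 and Arid3a (4 of 9), and against GC B cells for E2f2, Pld4, H2-Eb1, Aldoa, Ptpn6 and Rapgef1 (6 of 10). Isotype shares moved differently in plasma cells than in naive B cells for Ighm (−18.8 points), Ighg1 (9.38), Ighg2c (6.51), Ighg3 (−4.24) and the switched share (18.8), and differently than in GC B cells for Ighm (−20.1), Ighg1 (7.51), Ighg3 (−2.92), Ighe (0.334) and the switched share (20.1), with adjusted p between 0.00932 and 0.0354 (exact permutation of the genotype, 24 tests).

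Single libraries stood apart from the other 7 of their group in 33 of 336 sets of values, where chance gives about 1 in 20, or 16.8 (Dixon ratio of the gap to the range). In control naive B cells these included NK markers of mouse 4 (0.563), Ly6a of mouse 12 (0.527) and H2-T22 of mouse 10 (0.582), and in transgenic naive B cells T cell markers (0.531) and erythroid markers (0.690, 357 CPM against 9.67 to 117) of mouse 6 and Serpina3g of mouse 16 (0.533). In control GC B cells mouse 12 had total UMIs (0.624), genes detected (0.623) and NK markers (0.704) apart, with T cell markers of mouse 4 (0.684), dendritic cell markers of mouse 9 (0.621) and the Ighg2b share of mouse 3 (0.553). Transgenic GC B cells of mouse 8 stood apart in platelet markers (0.531), Cyp4f18 (0.620), Bcl6 (0.575), Cd79a (0.529), Cd22 (0.572), Ms4a1 (0.534), Cd74 (0.537) and H2-DMb2 (0.709), those of mouse 16 in Tpi1 (0.561) and Eno1 (0.725), and those of mouse 15 in Relb (0.533). Control plasma cells stood apart in Rel of mouse 2 (value 1, the one library with a Rel UMI), its Ighg3 share (0.582), erythroid markers of mouse 1 (0.927, 579.7 CPM against 4.16 to 46.0), the Ighe share of mouse 11 (0.532), Nfkb2 of mouse 4 (0.530) and Itga4 of mouse 10 (0.614). Transgenic plasma cells did so in monocyte, macrophage and neutrophil markers of mouse 15 (0.756, 127 CPM against 17.1 to 43.8), Mki67 of mouse 16 (0.625) and Foxp1 of mouse 8 (0.547).

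In transgenic plasma cells 178 genes other than immunoglobulin genes were called lower, with a median log2 fold change of −0.58. Less RNA of naive B cells in these libraries does not explain the whole pattern, since 95 transcripts abundant in naive B cells and at least 8 times lower in plasma cells had a median of −0.13, a ratio of 0.226 (jackknife SE 0.128) to that of the 178 genes. The 178 genes were picked for falling, which lowers this ratio. Of the 95 transcripts 68 had a negative fold change, and 17 were called lower and 1 higher, against 183 lower and 105 higher of all 4538 genes. Such RNA may thus add to the pattern. A lower share of IgM plasma cells is a candidate explanation that stays open. The relation of each gene to the Ighm share within genotypes was applied to the difference in that share. It gave 0.538 of the observed median (SE 0.322, 0.485 to 0.844 with 1 mouse left out). This value met the bound written before it was seen (at least 0.5). It did not meet a requirement, added after it was seen, that it exceed 0 by 2 SE. For Relb, Nfkb2, Nfkbia and Nfkbie alone the ratio was 1.11, without an SE, so nothing is concluded from it. Control mouse 4, with the highest Ighm share in plasma cells (54.5%), also stood apart in Nfkb2. A direct effect of c-Rel on these genes was not tested apart from the genotype and stays open.

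Libraries of naive B cells held switched heavy chain transcripts at a median of 6907 CPM, 2.89% of the level in the plasma cells of the same mouse, although the sort for high IgD would remove plasma cells. RNA of plasma cells is a candidate source: Jchain UMIs per switched UMI were similar in naive and plasma cell libraries (median log2 ratio −0.24, SE 0.327, from −2.39 to 1.68 over 16 mice), and Jchain, Derl3 and Sdc1 stood at 3.22, 4.01 and 6.19% of their plasma cell levels, with Tnfrsf17 at 1.43% and Prdm1 at 0%. Mzb1 at 12.1% and Xbp1 at 10.9% stood higher than such RNA alone would bring. Whether it came from the same mouse stays open, since switched isotype profiles were closer to the mouse's own plasma cells than to others of its genotype by 0.149 in correlation (one-sided permutation p = 0.202, 100000 resamples) and 2 of 16 naive libraries were closest to their own. Switched B cells within the naive gate were not tested and may add to it. The same RNA may raise the secretory, plasma cell and immunoglobulin lists in transgenic naive B cells, which was not tested. It may also add to the switched share of GC B cells, with a median of 4205.5 CPM, 1.90% of the plasma cell level. Their isotype profiles were closer to the mouse's own plasma cells by 0.180 (one-sided permutation p = 0.105), and 2 of 16 were closest to their own. This source stays open there.

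GC B cells and plasma cells shared 39 genes called in the same direction, 15 higher and 24 lower (3.59 and 6.09 for independent lists, which does not allow for the shared mice), among them Tgtp1, Ifi47 and Igtp upward and Foxp1, Relb and Cd74 downward. Different numbers of males and females are argued against as the whole cause by the near balance of the genotypes, as Xist marked 3 control and 4 transgenic mice as female. The median change in plasma cells with a covariate for Y-linked genes was 1.02 times that without (SE 0.133). With the sexes so near balance this ratio could hardly have moved, so it adds little. GC B cell RNA in the plasma cell libraries would make up a small part of the level of most of these genes in control mice. Their median ratio of plasma cell to GC B cell CPM there was 7.98 times what abundant GC genes allow (6.23 to 10.2 by resampling genes), although 10.3% of the genes lay within 2 times of that level. Its part in the genotype changes stays open. The genes had to be expressed and called in plasma cells, which favors a high ratio, and transgenic libraries were not measured in this way. A genotype effect common to both populations is 1 candidate for the 39 genes, as a hypothesis from the data it was found in. It was not tested, and the 2 populations come from the same mice. An earlier choice of pattern, the interferon list, was dropped without a test because few of its members were called.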

How the results depend on the processing

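The fits of mice 1 to 8 and of mice 9 to 16 alone were chosen after the data were seen, and the other settings before. No named gene reversed its direction in the settings in which it was tested. Other called genes were not followed singly, and a few had opposite signs in the blocks of mice 1 to 8 and 9 to 16. Counts in naive B cells moved most, from 24 to 13 with DESeq2, 11 with thinned counts and 0 by edgeR with all 48 libraries in 1 fit (592 at an unadjusted p under 0.05), where the 3 populations share 1 dispersion per gene and 7744 instead of 2131 genes were tested (the 2 were not told apart), and to 11 and 2 in the blocks of mice 1 to 8 and 9 to 16 alone. The blocks gave 55 and 198 genes in GC B cells and 71 and 106 in plasma cells, with 4 mice against 4. Leaving out each library gave 13 to 31 genes in naive B cells (13 without transgenic mouse 6, 15 without transgenic mouse 15), 340 to 747 in GC B cells (747 without transgenic mouse 8) and 212 to 320 in plasma cells. No expression filter gave 4408 genes for GC against naive B cells, 4536 for plasma cells against naive B cells and 7149 for plasma cells against GC B cells, from more genes tested, with 58.7 and 64.1% higher in the first 2 instead of 50.0 and 49.8% and median shifts of 0.27 and 0.36, and in naive B cells 78.6% of 28 instead of 54.2% were higher. Thinned counts gave 1326 genes for GC and 1068 for plasma cells against naive B cells (shift −0.14), and plasma cells against naive B cells gave 3841 with all 48 libraries and 1522 without control mice 9 and 10, with fewer genes tested. Differences between effects went from 10 to 16 without filter, 30 with DESeq2 and 19 with limma-voom (GC against naive B cells), and with thinned counts from 90 to 36 and from 122 to 16. With the mouse as a block the paired counts were 2660, 2505, 3948, 12, 86 and 148, none moving by over 1.5 times. Lists called went from 4 to 0, 8 to 1 and 7 to 2 with an estimated correlation, and from 8 to 4 with fry in GC B cells. The correlation of naive B cells with plasma cells went from 0.103, with 6 of 100 splits as large (the real one included), to 0.116 with 3 of 100 when immunoglobulin genes were left out. Other settings kept counts in GC B cells between 386 and 577, in plasma cells between 196 and 380 and in naive B cells between 17 and 28. Of the named genes 0 of 20 in naive B cells, 42 of 51 in GC B cells and 29 of 45 in plasma cells kept the call in every setting chosen before in which they were tested. Fits with 1 library left out are not counted in these numbers. Mice 1 to 8 alone kept 9 of 20, 16 of 49 and 22 of 42 of those tested, and mice 9 to 16 alone 1 of 20, 36 of 50 and 23 of 45. The loss of 1 library ended the call for 12, 8 and 8. Apart from settings with fewer genes or samples the cause was not tested.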

Other observations

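The comparisons of mice 1 to 8 with mice 9 to 16 and the values of the marker lists without single genes were chosen after the data were seen, and the marker lists before.

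Markers of cells outside the sorted populations were present at low levels. Some sums rested mostly on a single gene, so they do not by themselves show that such cells were present. In control naive B cells Tyrobp gave 63.9 of the 74.2 CPM of monocyte, macrophage and neutrophil markers, with Lyz2 at 2.33 CPM. Summed as log2(CPM + 1), in control and transgenic mice and with adjusted p over 33 exact permutation tests, NK markers were 3.48 and 1.67 in naive B cells (adjusted p = 0.355), 1.01 and 1.20 in GC B cells and 3.11 and 3.29 in plasma cells (adjusted p = 0.845 each). Monocyte, macrophage and neutrophil markers were 6.10 and 5.97, 4.49 and 4.45, and 5.21 and 5.09 in the same order (adjusted p = 0.918 in GC B cells and 0.845 in plasma cells), and erythroid markers 6.12 and 5.87, 7.80 and 7.51, and 4.39 and 3.45 (adjusted p = 0.575 in plasma cells). Platelet markers were not seen in naive B cells and stood at 0.847 and 0.671 in GC B cells and 1.42 and 2.10 in plasma cells (adjusted p = 0.322). T cell markers in naive B cells were 6.68 and 5.97 (adjusted p = 0.12), and dendritic cell markers there 6.08 and 6.30 (adjusted p = 0.642). In plasma cells the T cell genes Thy1, Trbc2 and Lat were at 24.1, 19.9 and 27.1 CPM in controls and 5.26, 8.63 and 10.5 CPM in transgenic mice, whereas Cd28 was at 78.8 and 91.8 CPM. Y-linked genes were 4.46 and 3.24 in naive B cells, 4.31 and 3.50 in GC B cells and 3.51 and 3.66 in plasma cells (adjusted p = 0.575, 0.845 and 0.952), and Xist marked 3 control and 4 transgenic mice as female.

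Mice 1 to 8 and mice 9 to 16 were compared in their genotype effects. The 2 sets of effects correlated across genes, which are not independent replicates, at 0.266 in naive B cells (2045 genes), 0.469 in GC B cells (6282 genes) and 0.530 in plasma cells (4243 genes). Of the genes called in mice 1 to 8, 10 of 11, 55 of 55 and 70 of 71 had the same sign in mice 9 to 16, and of those called in mice 9 to 16 and tested in the others 1 of 2, 186 of 189 and 95 of 95. Compared with each other at equal genotype, the 2 blocks of mice differed by edgeR in 0 genes in naive B cells (95 at an unadjusted p under 0.05), in 11 in GC B cells and in 20 in plasma cells, with the cell cycle genes Cenpa and Plk1 in GC B cells and Ube2c and Birc5 in plasma cells among them.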
